A study of Arabidopsis thaliana with 11 samples.

How the data were processed

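Transcript levels were measured on 11 Affymetrix ATH1 arrays, each hybridised with RNA from whole Arabidopsis seedlings kept in darkness and collected when 4 days old. The seedlings were of 2 genotypes, the Col wild type and the arf2 mutant, which is mutated in the gene for the auxin response factor ARF2. They grew with 0.5 µM brassinazole (BRZ, an inhibitor of brassinosteroid synthesis) or on mock medium. There were 3 replicate arrays each for Col on mock, Col on BRZ and arf2 on mock, and 2 for arf2 on BRZ. The submitters had left out 1 further array of that group after their quality control with simpleaffy.

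The deposited values are gcRMA intensity estimates per probe set, as the authors computed them, with background correction and normalization between arrays inside that method. They state no version. The deposited intensity values were on a linear scale, so their log2 was taken first. Arrays give no counts, and the number of arrays per group limits the precision.

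Of 22810 probe sets, 64 were controls and were kept out of the tests. A further 860 probe sets did not exceed a log2 value of 4 on at least 2 arrays and were dropped, which left 21886. The supplied annotation names 1 gene for 13513 of the 22746 other probe sets and several genes for 503. It names none for 8730 of them (38.4%). The tested probe sets covered 12707 genes. No probe set was named for ARF2 or for any gene of brassinosteroid synthesis, so the level of ARF2 was not analysed here. Gene order on the chromosomes and gene names came from the supplied gene table of the TAIR10.1 assembly.

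All 11 arrays went into 1 linear model in limma 3.58.1 under R 4.3.3, with 1 mean per group. Each probe set had 1 moderated residual variance, shared by all groups. The adjusted p is limma's two-sided moderated p after Benjamini-Hochberg correction over the probe sets tested, and a probe set was called when it was under 0.05. The comparisons were BRZ with mock in Col, BRZ with mock in arf2, arf2 with Col on mock, arf2 with Col on BRZ, and the interaction, which is the BRZ effect in arf2 minus that in Col. An average of both BRZ effects, weighted by their precision, served to choose probe sets for comparing the 2 genotypes. Errors of log2 changes are standard errors (SE) from the model. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

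The comparisons, the tests, the naming rule, 30 gene lists and most alternatives were chosen before the data were examined. By that rule the named genes were the 10 with the largest rise and the 10 with the largest fall in each comparison, among called probe sets that name exactly 1 gene. They also had to exceed a log2 value of 4 on every array of at least 1 of the groups compared. Except for the interaction, all arrays of one group had to lie above all arrays of the other. Members of the gene lists could be named too. Of the 30 lists, 6 had at least 4 measured genes and were tested with camera at a preset correlation of 0.01 between genes, adjusted over lists. These were expansins (19 of 37 genes measured), xyloglucan endotransglucosylases (10 of 33) and Aux/IAA repressors (6 of 29). The others were GH3 conjugating enzymes (5 of 9), nuclear photosystem subunits (4 of 27) and chlorophyll biosynthesis (4 of 12). All list results below cover the measured members only. A gene counted as measured when a tested probe set named it alone. For 13 lists the annotation names no probe set for any single member, so these lists were not analysed. Unnamed probe sets may still measure their genes. A further 23 gene families were defined after the annotation had been seen and before any test of them. They were adjusted as a set of their own.

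Alternatives were no filter, stricter filters, quantile normalization, equal array medians, a floor at a log2 value of 4, a trend with robust variances, array weights, the replicate number as a block and removal of probe sets that cross-hybridise. Further ones were each of the 11 arrays left out, a 2-fold minimum, an adjusted p under 0.01, fits of only the 2 groups compared, a correlation between genes estimated from the data and the mean of all probe sets of a gene. A filter at a log2 value of 5 and leaving out 2 or 3 arrays that stood apart, in 3 sets, were added after seeing the data. Whether replicate numbers pair the arrays was not settled. After subtraction of group means, the 15 pairs of arrays with the same number in different groups correlated between -0.59 and 0.14. Between Col mock and Col BRZ the same number gave 0.12, 0.09 and 0.14, and different numbers gave -0.08 to -0.04. Between Col mock and arf2 mock the same number gave 0.11, -0.40 and -0.59. The block was used only as an alternative, so a pairing within Col is not taken up in the main fit.

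The procedure was tested on simulated data with independent noise of the same variance on every array. The real arrays differed in spread and some departed together, so the rates below hold for such simulated arrays only. Among probe sets that were not moved, the procedure made 6 to 16 false calls per comparison. Of probe sets moved by log2 1 it called 98% for BRZ in Col, 95% for BRZ in arf2, 98% for arf2 on mock, 92% for arf2 on BRZ and 71% for the interaction.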

Results

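Gene expression was measured in dark-grown seedlings of the Col wild type and the arf2 mutant with and without BRZ, which blocks brassinosteroid synthesis. The 11 arrays comprised 3 of Col on mock, 3 of Col on BRZ, 3 of arf2 on mock and 2 of arf2 on BRZ.

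The arrays did not all share 1 level. The median log2 value of the tested probe sets was 5.96, 5.93 and 6.20 on Col mock arrays 1, 2 and 3. It lay between 6.20 and 6.22 on the Col BRZ arrays. On arf2 mock it was 6.22, 6.22 and 6.09, and on arf2 BRZ it was 6.23 and 6.28. Col mock array 2 and arf2 mock array 3 departed from their group means together, with a correlation of 0.60 across probe sets, which are not independent replicates. The control probe set for 25S ribosomal RNA read 263, 193 and 173 on arf2 mock, 95.9, 59.7 and 77.3 on Col mock, 97.2, 85.3 and 131 on Col BRZ, and 33.6 and 63.9 on arf2 BRZ.

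**Figure D1:**
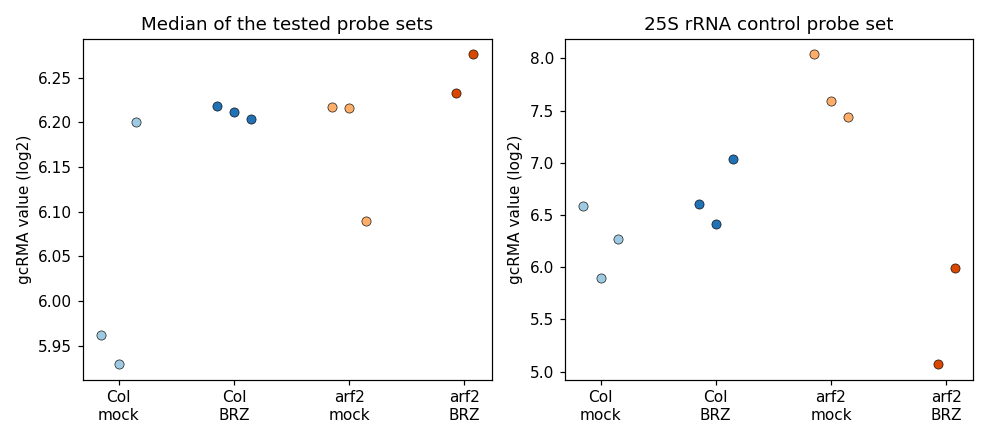
Per-array medians of the tested probe sets (left) and level of the 25S rRNA control probe set (right), both on the log2 scale, with 1 point per array in each of the 4 groups. Col mock arrays 1 and 2 have the lowest medians (5.96 and 5.93), and the 3 arf2 mock arrays have the highest 25S rRNA values.

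The first comparison asked which transcripts depend on brassinosteroid synthesis in the wild type. On BRZ, AT1G75900, a GDSL lipase, fell from an intensity of 942 to 130 (log2 change -2.85 ± 0.11 SE, 3 arrays against 3, adjusted p 3.59e-07). AT2G16005, a lipid-recognition protein, fell 13.3-fold (-3.73 ± 0.22, adjusted p 3.2e-06), to a level only a little above the lower quartile of the arrays. The peroxidase AT4G36430 fell 6.77-fold (-2.76 ± 0.28, adjusted p 0.00013), and the cysteine proteinase CP1 (AT4G36880) fell 4.41-fold (adjusted p 5.35e-06). In the other direction, GH9B8 (AT2G32990), an endoglucanase family member, rose 4.27-fold (SE of the log2 change 0.15, adjusted p 1.28e-05). Another peroxidase, AT5G15180, rose 5.23-fold (2.39 ± 0.12, adjusted p 1.84e-06). AT5G22580 rose 7.54-fold, AT3G05730 rose 8.18-fold, and the sugar transporter SWEET1 (AT1G21460) rose 3.63-fold (1.86 ± 0.31, adjusted p 0.00371).

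Expansins, which loosen cell walls, shifted downward as a list in Col on BRZ. Of 19 measured members 5 fell, 1 rose and 13 did not pass (1 up and 6 down adjusted over the list alone), and camera gave an adjusted p of 4.96e-05. With an estimated correlation the adjusted p was 0.174. EXPA4 fell by 1.36 on the log2 scale (SE 0.09, adjusted p 5.97e-06) and EXLB1 fell by 1.35 (SE 0.13, adjusted p 8.99e-05). EXPA9 rose by 0.51 (SE 0.10, adjusted p 0.00921), a call that equal array medians ended (adjusted p 0.08), as did leaving out Col mock arrays 1 and 2 (adjusted p 0.192, or 0.145 without arf2 mock array 3 as well). Of 10 measured xyloglucan endotransglucosylases, which remodel wall polymers, 4 rose, 1 fell and 5 did not pass (5 up and 2 down adjusted over the list alone). That list was not called (adjusted p 0.262). XTH16 (AT3G23730) rose by 1.75 (SE 0.19, adjusted p 0.000247) and XTH32 by 1.40 (SE 0.19, adjusted p 0.00115). GH3.3 (AT2G23170), an enzyme that conjugates auxin to amino acids, rose by 0.93 (SE 0.10, adjusted p 0.000216). The other 4 of the 5 GH3 genes did not pass (1 up and 1 down adjusted over the list alone), and the list had an adjusted p of 0.74. The 4 measured of 27 nuclear photosystem genes were called upward as a list (adjusted p 0.0285, or 0.485 with an estimated correlation). PSAN was the 1 that rose by itself (0.58, SE 0.10), with 2 up adjusted over the list alone. This photosystem call was lost without Col mock array 2 (adjusted p 0.0589) or array 3 (adjusted p 0.0751), with array weights (0.0574) and with filters at 5 (0.071) and 6 (0.0799). It was also lost without Col mock array 2 and arf2 mock array 3 (0.0858), and without Col mock array 1 as well (0.0683). Aux/IAA repressors (adjusted p 0.578) and chlorophyll biosynthesis (adjusted p 0.465) were not called, with 1 of 6 and 1 of 4 measured members up, the same over the list alone.

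In all, limma called 1956 probe sets between BRZ and mock in Col, 1357 higher and 599 lower, of which 243 changed at least 2-fold. The share that was higher, 69.4%, was 49.0% after quantile normalization (933 higher, 970 lower) and 34.8% with equal array medians (626 higher, 1172 lower). Equal medians moved the median log2 change of all tested probe sets from 0.06 to -0.12. A fit of only Col mock and Col BRZ, with the variance of these 2 groups alone, gave 959 calls. The count was 5084 without Col mock array 3, 1125 without Col mock array 1, and 1040, 1159 and 936 without Col BRZ arrays 1, 2 and 3. Leaving out Col mock arrays 1 and 2 gave 658, and leaving out arf2 mock array 3 as well gave 903.

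**Figure D2:**
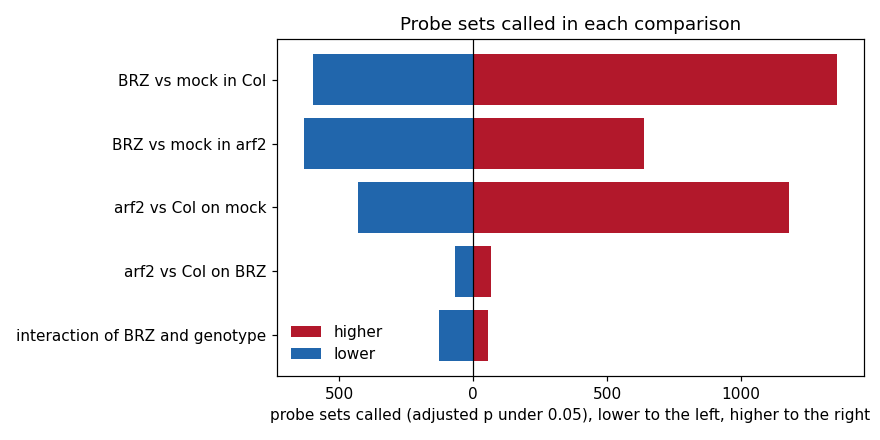
Number of probe sets called higher (right) and lower (left) in each of the 5 comparisons, at an adjusted p under 0.05. BRZ in Col gave 1357 higher and 599 lower calls, and the arf2 comparison on BRZ gave 65 and 70.

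The same question was put to the mutant. AT1G75900 fell 7.68-fold in arf2 on BRZ (-2.94 ± 0.12, 2 arrays against 3, adjusted p 3.2e-07), next to 7.23-fold in Col. GH9B8 rose 6.95-fold (adjusted p 4.61e-06), AT5G01740 rose 10.5-fold (3.40 ± 0.15, adjusted p 4.87e-07) and AT5G22580 rose 8.58-fold. XTH16 rose by 1.75 on the log2 scale (SE 0.22, adjusted p 0.000567), and XTH32 by 1.42 (SE 0.22). Among genes that meet the naming rule, the deepest fall was that of AT1G26380, an oxidoreductase of the berberine bridge family (-3.50 ± 0.26, adjusted p 2.21e-05). Only 611 of the 1271 calls name 1 gene. The deposited values of AT1G26380 on the 2 arf2 BRZ arrays were identical (intensity 41.7), as were those of 2.24% of probe sets. AT3G13610, an enzyme of coumarin synthesis, fell by 2.69 (SE 0.31, adjusted p 0.000327). AT4G18280 fell 8.68-fold. On the same arrays 25S rRNA differed by a log2 change of -2.15 (exact permutation p 0.1, the smallest that 2 arrays against 3 allow).

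Among expansins in arf2 on BRZ, EXLB1 fell by 1.26 (SE 0.14, adjusted p 3e-04) and EXPA4 fell by 0.56 (SE 0.10, adjusted p 0.00653), while 17 of 19 did not pass. The EXPA4 call was lost without arf2 BRZ array 1 (adjusted p 0.075). The list was called downward (adjusted p 0.0196, or 0.682 with an estimated correlation). That call was lost with equal array medians (adjusted p 0.059), with the filter at 6 (0.0535), without arf2 mock array 3 (adjusted p 0.0922) and without arf2 BRZ array 2 (adjusted p 0.215). It was also lost without Col mock array 2 and arf2 mock array 3 (0.0907), and without Col mock array 1 as well (0.125). The other 5 lists were not called, their adjusted p running from 0.51 for xyloglucan endotransglucosylases to 0.699 for GH3 enzymes.

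BRZ against mock in arf2 gave 1271 calls, 638 higher and 633 lower, with 314 of at least 2-fold. Equal array medians gave 464 higher and 813 lower. The count was 503 and 532 without arf2 BRZ arrays 1 and 2, where the array that remained was assumed to vary like the other groups, and 769 without arf2 mock array 1. It was 2199 without Col mock arrays 1 and 2 and arf2 mock array 3.

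Much of the response was shared. Both genotypes called 596 probe sets, of which 580 moved the same way, 346 up and 234 down, where independent calls would give 39.6 and 17.3. AT1G75900, GH9B8, AT5G22580 and XTH16 were among these. Across probe sets, which are not independent replicates, the 2 BRZ effects correlated at r = 0.58 (Spearman's rho 0.56). Among 3534 probe sets called in the averaged response (2402 higher, 1132 lower), the slope of the arf2 effect on the Col effect was 0.74 (jackknife SE 0.193). The slope of the Col effect on the arf2 effect was 0.72, under 1 as well. Scatter between the effects lowers both slopes, and noise was not told apart from real differences between the genotypes. The interaction was called for 137 of these probe sets. A smaller effect in arf2 was found for 57.8% (jackknife SE 19.3). For the 208 of these with a 2-fold averaged change, the slope of arf2 on Col was 0.83 and the share 51.0%. With equal array medians the averaged response had 1102 higher and 2193 lower, and with quantile normalization 1660 and 1570. The share with a smaller effect was 48.0% without Col mock array 2 and 33.9% without Col mock arrays 1 and 2, so a weaker response in arf2 was not established. The shared count was 276 and 291 without arf2 BRZ arrays 2 and 1, 372 without arf2 mock array 1 and 380 without Col BRZ array 3.

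The third comparison asked what the arf2 mutation changes with brassinosteroid synthesis intact. In arf2 on mock AT1G26380 was 15.3-fold higher than in Col (3.94 ± 0.24, 3 arrays against 3, adjusted p 2.74e-06, intensity 470.0 against 30.7). Its relative AT1G26390 was higher too (adjusted p 9.83e-05), from a Col mock mean of 4.37 on the log2 scale, below the mean lower quartile of these arrays (4.53), so no fold is given. AT3G13610 was 10.3-fold higher (3.37 ± 0.28, adjusted p 2.56e-05). CCOAMT (AT1G67980), a methyltransferase of phenylpropanoid metabolism, was 6.99-fold higher (2.80 ± 0.19, adjusted p 6.13e-06). The peroxidase AT1G14550 was higher (adjusted p 0.000307), also from a Col mock mean of 4.37, so no fold is given. The lectin-like AT3G16530 and the protease inhibitor AT2G38870 were higher by 2.24 and 2.11 on the log2 scale. QQS (AT3G30720), a gene linked to starch content, was 6.46-fold higher (2.69 ± 0.11, adjusted p 1.52e-07). AT2G16005 was 13.6-fold lower (-3.77 ± 0.22, adjusted p 2.11e-06), at a level in arf2 only a little above the lower quartile of the arrays. AT1G55240 was 11.4-fold lower (-3.52 ± 0.17, adjusted p 4.29e-07), and the pectin methylesterase PME61 (AT3G59010) was 2.94-fold lower (-1.56 ± 0.10, adjusted p 3.68e-06). In the same arrays 25S rRNA was higher by 1.44 on the log2 scale (exact permutation p 0.1, the smallest that 3 arrays against 3 allow).

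In arf2 on mock 3 of the 6 lists were called downward. Among expansins 4 fell, 1 rose and 14 did not pass (2 up and 4 down adjusted over the list alone; adjusted p 0.00258, or 0.162 with an estimated correlation). EXPA4 fell by 1.22 (SE 0.09, adjusted p 1.32e-05) and EXPA16 by 0.83 (SE 0.13, adjusted p 0.00248), whereas EXPA9 was higher by 0.69 (SE 0.10). GH3.3 was lower (-1.36 ± 0.10, adjusted p 1.32e-05), the 1 called of 5 GH3 genes, and that list had an adjusted p of 0.00137, or 0.089 with an estimated correlation. Of 10 xyloglucan endotransglucosylases 1 fell, XTH16 (-0.84 ± 0.19, adjusted p 0.0212), with 2 down adjusted over the list alone. That list had an adjusted p of 0.00258, or 0.089 with an estimated correlation. The XTH16 call was lost without Col mock array 1 (adjusted p 0.0523), arf2 mock array 1 (adjusted p 0.0863) and arf2 mock array 3 (adjusted p 0.0754), with array weights (0.081) and with the replicate block (0.0535). Without Col mock arrays 1 and 2 all 3 list calls were lost, at an adjusted p of 0.308 for expansins and 0.125 for both other lists, and so were the calls of XTH16 (0.0907) and EXPA16 (0.0548). With arf2 mock array 3 left out too, these were 0.0788 and 0.0648 for the lists and 0.132 for XTH16, which had 0.0767 without Col mock array 2 and arf2 mock array 3. Aux/IAA repressors, photosystem subunits and chlorophyll biosynthesis were not called (adjusted p 0.654, 0.534 and 0.178).

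Between arf2 and Col on mock 1609 probe sets were called, 1177 higher and 432 lower, with 287 of at least 2-fold. The higher share of 73.2% was 53.6% after quantile normalization (819 higher, 710 lower) and 44.3% with equal array medians (620 higher, 781 lower). A fit of only Col mock and arf2 mock, with the variance of these 2 groups alone, gave 663 calls. The count was 3040 without Col mock array 3, 882 and 1024 without arf2 mock arrays 1 and 2, and 830 without Col mock arrays 1 and 2 and arf2 mock array 3.

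The fourth comparison asked what the arf2 mutation changes when brassinosteroid synthesis is inhibited. QQS was 9.13-fold higher in arf2 on BRZ (3.19 ± 0.13, 2 arrays against 3, adjusted p 2.35e-07). The small heat shock protein AT1G53540 was higher by 1.61 and the lipid transfer protein AT1G62510 by 1.66 on the log2 scale. GH3.3 was 5.19-fold lower (-2.38 ± 0.11, adjusted p 1.09e-06), and AT1G55240 was 6.57-fold lower (-2.71 ± 0.19, adjusted p 5.74e-05). AT4G11190, a dirigent-like protein, was lower by a log2 change of -1.22 ± 0.13. The glutaredoxin AT4G15680 was lower as well (-1.48), a call lost without arf2 BRZ array 1 (adjusted p 0.121) or array 2 (adjusted p 0.057). On these arrays 25S rRNA was lower in arf2, with a log2 change of -1.15 (exact permutation p 0.1).

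**Figure D3:**
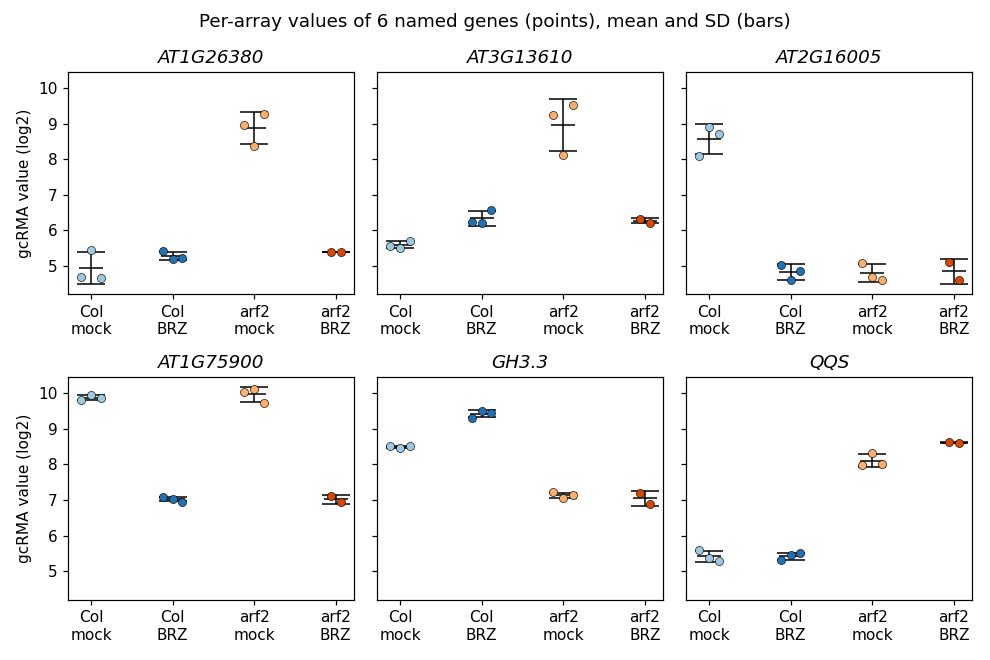
Log2 gcRMA value of 6 named genes on each array (points) in the 4 groups, with group mean and SD (bars). AT1G26380 and AT3G13610 are high on arf2 mock alone, AT1G75900 falls with BRZ in both genotypes, and QQS is high and GH3.3 low in arf2 on both media.

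On BRZ 4 lists were called downward in arf2, all at the preset correlation. For 10 xyloglucan endotransglucosylases the adjusted p was 0.000199 (0.059 with an estimated correlation), and XTH33 was the 1 that fell (-0.78 ± 0.13, 3 down adjusted over the list alone). The XTH33 call was lost without Col BRZ array 2 (adjusted p 0.0765), Col BRZ array 3 (adjusted p 0.0938) and arf2 BRZ array 2 (adjusted p 0.163), and with the replicate block (0.0947). For GH3 enzymes it was 0.00988 (0.142 with an estimated correlation). GH3.3 was the 1 that fell, and the median member had a log2 change of 0.01 against a mean of -0.51. Photosystem subunits had an adjusted p of 0.000938 (0.142 with an estimated correlation) and chlorophyll biosynthesis 0.0107 (0.191 with an estimated correlation), with 0 of 4 members passing in each list, or 1 and 2 adjusted over the list alone. Without arf2 BRZ array 1 the photosystem and chlorophyll calls were both lost (adjusted p 0.193), as was the chlorophyll call without Col BRZ array 1 (adjusted p 0.0969) and the GH3 call without arf2 BRZ array 2 (adjusted p 0.193). Expansins (adjusted p 0.16) and Aux/IAA repressors (adjusted p 0.876) were not called.

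Between arf2 and Col on BRZ 135 probe sets were called, 65 higher and 70 lower, with 54 of at least 2-fold, or 54 higher and 101 lower with equal array medians. A fit of only these 2 groups and array weights each gave more calls (given below). The shared variance includes that of the more variable Col mock arrays, so the counts on mock and on BRZ do not measure which genotype difference is larger. The count was 68, 72 and 62 without Col BRZ arrays 1, 2 and 3, 49 and 70 without arf2 BRZ arrays 1 and 2, and 256 without Col mock array 2. It was 338 without Col mock array 2 and arf2 mock array 3, and 675 without Col mock array 1 as well. QQS, GH3.3 and AT1G55240 belonged to 87 probe sets called the same way on mock and on BRZ, 42 higher and 45 lower, where independent calls would give 3.50 and 1.38.

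The interaction asked whether the BRZ effect differed between the genotypes. AT1G26380 fell in arf2 and had a log2 change of 0.34 ± 0.24 in Col (interaction -3.84 ± 0.35, adjusted p 0.000408). Its intensity was 30.7 in Col on mock, 38.9 in Col on BRZ, 470.0 in arf2 on mock and 41.7 in arf2 on BRZ. AT3G13610 and CCOAMT had interactions of -3.44 ± 0.41 and -2.13 ± 0.28 (adjusted p 0.00307 and 0.0047). AT2G16005 went the other way, falling with BRZ in Col from 379 to 28.5 and staying at 27.8 and 28.9 in arf2 (interaction 3.79 ± 0.33, adjusted p 0.000325). These low values lay only a little above the lower quartile of the arrays. A fall with BRZ thus had little room in arf2, and the size of the interaction depends on the background correction. PME61 fell by 1.63 in Col and rose by 0.75 in arf2 (interaction 2.37 ± 0.15, adjusted p 3.56e-05). GH3.3 rose by 0.93 in Col against a change of -0.09 in arf2 (interaction -1.02 ± 0.15, adjusted p 0.00893).

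For the interaction 184 probe sets were called, 55 positive and 129 negative. The interaction is taken from the same arrays as both BRZ effects, so calls shared with them are partly built in. Of the 184, the BRZ effect was called in arf2 alone for 94, in Col alone for 52, in both the same way for 20, in both in opposite ways for 16 and in neither for 2. In camera 0 of the 6 lists were called for the interaction, the lowest adjusted p being 0.104 for expansins, while expansins and photosystem subunits had an unadjusted p under 0.05 (0.0173 and 0.0438). Quantile normalization gave 101 positive and 136 negative calls. Array weights gave more calls and the replicate block fewer (given below). The count was 344 without Col mock array 3, 98, 95 and 112 without Col BRZ arrays 1, 2 and 3, and 62 and 103 without arf2 BRZ arrays 1 and 2.

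The effects of the arf2 mutation and of BRZ were compared across genes. In Col on BRZ and in arf2 on mock, each against Col on mock, AT2G16005, PME61 and EXPA4 fell in both. GH3.3 rose on BRZ and was lower in arf2, and CP1 fell on BRZ and was higher in arf2. Of 473 probe sets called in both, 204 were higher in both, 151 lower in both, 45 higher on BRZ and lower in arf2, and 73 the reverse. Across probe sets, which are not independent replicates, r was 0.30 (rho 0.40, jackknife SE of r 0.231). Both effects were taken against the same 3 Col mock arrays, and simulated data with no effects gave r = 0.50. The simulations gave each probe set the same variance on every array. Real replicate arrays differed with an SD of 0.26 to 0.42 in Col mock, against 0.16 to 0.19 in Col BRZ. Noise of the shared Col mock arrays is thus understated in all simulated values here, and an excess over them may come from it. The covariance was 0.0283, above the mean of these simulations by 0.0183. The jackknife SE of this excess, added after seeing the data, was 0.0348, so neither likeness nor opposition was established. At an unadjusted p under 0.05 in both, 78.7% of probe sets moved the same way, against 99.5% in those simulations, so these counts are no measure of similarity. The 2 effects averaged over the other factor, which share little, correlated at -0.08 (rho 0.09, jackknife SE of r 0.209), against 0.11 in simulations. Their covariance was -0.00481 against 0.00121 in simulations, a difference of -0.00602 (jackknife SE 0.0118). The correlation ranged from -0.18 without Col mock array 2 to 0.08 without Col mock array 3.

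Lists with fewer than 4 measured genes gave single values. COR47, a dehydration-induced gene, fell by 0.55 in Col on BRZ (SE 0.09, adjusted p 0.00255, or 0.0591 without Col mock arrays 1 and 2). The chaperone gene ATHSP22.0 was higher in arf2 on mock by 1.06 (adjusted p 0.0107, or 0.0541 without Col mock arrays 1 and 2 and 0.0789 in a fit of these 2 groups). The brassinosteroid signalling genes BIM1 and BRL1, the light-harvesting genes LHCB4.1, LHCB4.2 and LHCB4.3, the ethylene regulator EIN3, the cell wall gene COB and the stomatal genes SPCH, MUTE and FMA were called in none of the 5 comparisons.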

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

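The test of a shared growth or harvest batch was chosen only after the result was seen, the test without the 2 arrays that stood apart was set before it, and leaving out arrays together was an alternative added after seeing the data.

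The effect of BRZ differed between Col and arf2 for 184 probe sets, by limma's test of the interaction. Among named genes the BRZ effect was more negative in arf2 for AT1G26380 (-3.84), AT3G13610 (-3.44), AT3G05730 (-3.0), AT2G16630 (-2.79), AT1G26390 (-2.78), AT3G16530 (-2.71), AT2G34930 (-2.48), AT1G14550 (-2.37), AT5G43520 (-2.16) and CCOAMT (-2.13), all as log2 differences. It was more positive for AT2G16005 (3.79), PME61 (2.37), AT4G17470 (2.25), AT5G10770 (1.71), AT5G57785 (1.70), AT4G33550 (1.61), MTP11 (1.30), AT3G29410 (1.25), AT4G11190 (1.22) and AT5G60760 (1.22). AT3G05730 is one that rose in Col and changed by 0.03 in arf2, while AT5G10770 rose by 1.73 in arf2 and changed by 0.02 in Col. The sizes for AT1G26390 and AT1G14550 depend on the background correction, since outside arf2 mock their means (4.27 to 4.39 and 4.37 to 4.46) lay near or below the lower quartile of the arrays (4.46 to 4.53). AT2G16005 lay only a little above that quartile outside Col mock, so its size depends on it too. AT3G29410 had the same deposited value (log2 5.42) on all 3 arf2 mock arrays and on Col BRZ array 1, and AT1G26380 (5.38) on both arf2 BRZ arrays, so their spread there is understated.

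Leaving out 1 array ended some of these interaction calls. Without arf2 BRZ array 1 the adjusted p was 0.181 for MTP11, 0.119 for AT3G29410, 0.0641 for AT4G11190, 0.0889 for AT3G05730, 0.0602 for AT1G26390, 0.0566 for AT3G16530 and AT5G43520, 0.0715 for AT2G34930 and 0.131 for AT1G14550. Without arf2 BRZ array 2 it was 0.0672 for MTP11, 0.101 for AT5G60760, 0.0736 for AT1G26390, 0.0981 for AT1G14550 and 0.0872 for AT5G43520. For MTP11 it was 0.0752, 0.0519 and 0.0567 without Col mock array 1 and Col BRZ arrays 1 and 2. For AT1G14550 it was 0.0647 without Col mock array 1, 0.0577, 0.0822 and 0.0714 without Col BRZ arrays 1, 2 and 3, and 0.056 without arf2 mock array 2. For AT5G60760 it was 0.085 without Col mock array 1, 0.0804, 0.0982 and 0.11 without the Col BRZ arrays, and 0.0742 and 0.0728 without arf2 mock arrays 1 and 2. AT3G29410 had 0.0718 without Col mock array 1, 0.0693, 0.0902 and 0.0714 without the Col BRZ arrays, and 0.0708, 0.0593 and 0.0546 without the arf2 mock arrays. AT5G43520 had 0.0552 without Col BRZ array 2. The replicate block gave 0.105 for MTP11, 0.109 for AT5G60760, 0.0811 for AT3G29410, 0.0659 for AT5G43520 and 0.0516 for AT3G05730. Without Col mock arrays 1 and 2 the adjusted p was 0.0616 for MTP11, 0.0753 for AT5G60760, 0.137 for AT3G29410 and 0.109 for AT1G14550, and with arf2 mock array 3 left out too 0.0506, 0.0536, 0.147 and 0.0788.

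Gene families were called for the interaction too, as lists, in camera at the preset correlation. Called toward a lower BRZ effect in arf2 were the lists of 69 chloroplast-encoded genes (adjusted p 2.48e-05, or 0.661 with an estimated correlation) and of 22 nuclear-encoded thylakoid proteins (adjusted p 0.00464, or 0.647 with an estimated correlation). The thylakoid list shares genes with the list of nuclear photosystem subunits (the same median of -0.28 in each), so it is not independent of that list. Called toward a higher one were the lists of 7 tubulins (adjusted p 0.000483, or 0.211 with an estimated correlation), 4 jacalin lectins (adjusted p 0.00144, or 0.211 with an estimated correlation) and 9 RALF-like peptides (adjusted p 0.0461, or 0.243 with an estimated correlation). No member of these 5 families was called over all probe sets, and 2 of the 4 jacalin lectins were higher adjusted over the list alone. Without arf2 BRZ array 1 the chloroplast call was lost (adjusted p 0.568), as was the thylakoid call (0.717). Without Col mock arrays 1 and 2 both were lost again (0.253 and 0.399). The thylakoid call was also lost without Col mock array 2 (0.0878), arf2 mock array 1 (0.0629), Col mock array 2 with arf2 mock array 3 (0.0749), and these 2 with Col mock array 1 (0.333). The RALF call was lost with quantile normalization (0.0763), with equal array medians (0.0627) and without any single array but Col BRZ array 3, arf2 mock array 2 and arf2 BRZ array 2, with adjusted p up to 0.167 without Col mock array 2. It was lost too with array weights (0.0978), with the floor at 4 (0.0503) and in the 3 sets of arrays left out together (0.11 to 0.308).

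Among the interaction calls were 93 probe sets, 45 of them naming 1 gene, that were higher in arf2 than in Col on mock and fell with BRZ in arf2, AT1G26380, AT3G13610 and CCOAMT among them. Their median log2 change was 1.38 between the genotypes on mock and 0.10 on BRZ. It was -1.35 with BRZ in arf2 and 0.08 with BRZ in Col, where 8 were called higher and 10 lower. The choice by these calls enlarges the values of 1.38 and -1.35. A called interaction was required too, which favours probe sets with little genotype difference on BRZ and no fall with BRZ in Col. The values of 0.10 and 0.08 are thus partly built in. The 25S rRNA control moved alongside on mock and with BRZ in arf2 (log2 changes of 1.44 and -2.15), and unlike them it was also lower in arf2 than in Col on BRZ (-1.15). Distortion of Col mock array 2 and arf2 mock array 3 was tested by leaving both out. The median interaction was then 102% of its value over all arrays, and 87 of the 93 were still called. So the members did not rest on these 2 arrays alone. Leaving out any single array also kept at least 93.6%. The members were chosen by calls that need agreeing replicates, so a large fall was unlikely beforehand and distortion is not excluded. A batch of the arf2 mock seedlings is a candidate explanation that could not be excluded, since no label names a batch, and that 98.9% of the 93 lay higher on all 3 arf2 mock arrays than on each of the other 8 nearly follows from how they were chosen and decides nothing; the relation to 25S rRNA, and a dependence of these genes on both ARF2 and brassinosteroid synthesis, which the design names, also stayed open.

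The control probe set for 25S ribosomal RNA, outside the measurements compared, was higher on arf2 mock than on Col mock arrays by 1.44 on the log2 scale (exact permutation p 0.1, the smallest possible with 3 against 3). With BRZ in arf2 its log2 change was -2.15 and with BRZ in Col 0.43 (exact permutation p 0.1 and 0.2).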

How the results depend on the processing

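Leaving out 2 or 3 arrays that stood apart and the filter at 5 were added after seeing the data, and all other settings were chosen before. Over 29 settings, 331 of 416 values of the main results counted as unchanged, and 85 did not. Counts were unchanged when they stayed within 1.5 times. The slope, the share with a smaller response and the correlations were unchanged when they stayed within their jackknife SE. That SE comes from the same fits without 1 array, so those fits could hardly move these values, which raises the 331. Of 328 called values of named genes and list members, 7544 of 8794 repeats were called in the same direction, 1250 were not called and 0 reversed. For gene lists 3537 repeats stood as before, 115 lost and 69 gained a call, and 4 turned direction with a call on one side. Where no cause is given, the cause was not tested. The GH3 and jacalin lists fell under 4 genes with stricter filters and gave no value there. Signal near background limits genes that are dim in some groups, which the filter keeps, and the size of their changes. Examples are AT1G26390 (4.37 on Col mock), AT1G14550 (4.37) and, outside Col mock, AT2G16005.

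The filter at 6 gave 204 calls for arf2 on BRZ and 1, 0 and 1 lists for BRZ in Col, BRZ in arf2 and the interaction. Equal medians gave 0 lists for BRZ in arf2. Array weights gave 2693 calls for BRZ in arf2, 903 for arf2 on BRZ, 301 for the interaction and 1 list for BRZ in Col. The replicate block gave 783, 66 and 84 for these 3 comparisons and 373 shared BRZ calls. Leaving out Col mock 2 and arf2 mock 3 gave 338 calls for arf2 on BRZ and 1 and 0 lists for BRZ in Col and in arf2. Leaving out Col mock 1 as well gave 903 and 2199 calls for BRZ in Col and arf2, 830 and 675 for arf2 on mock and BRZ, 0 lists for BRZ in arf2 and arf2 on mock, and called the interaction of AGAMOUS-like genes (adjusted p 0.013) against the direction it had, uncalled, over all arrays. Leaving out only Col mock 1 and 2 gave 658, 2198 and 333 calls for BRZ in Col, BRZ in arf2 and arf2 on BRZ, 726 calls and 0 lists for arf2 on mock, 33.9% with a smaller response in arf2, and an adjusted p of 0.0207 for AGAMOUS-like genes, turned likewise. Stricter thresholds lower counts by construction. A 2-fold minimum gave 243, 314, 287 and 54 calls for the 4 group comparisons, 208 averaged and 103 shared. An adjusted p under 0.01 gave 771, 556, 726, 57 and 73 calls, 1577 averaged and 244 shared. Fits of only 2 groups use fewer arrays and the variance of those groups alone. They gave 959 for BRZ in Col, 663 for arf2 on mock and 372 for arf2 on BRZ. Replicate arrays differed with an SD of 0.26 to 0.42 in Col mock, 0.16 to 0.19 in Col BRZ and 0.20 in arf2 BRZ. The variance shared by all groups may thus be too small for comparisons with Col mock and too large for arf2 on BRZ. With an estimated correlation 0 lists were called in each of the 4 group comparisons.

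Leaving out each array in turn gave 936 to 5084 calls for BRZ in Col, 503 to 1825 for BRZ in arf2, 882 to 3040 for arf2 on mock, 49 to 256 for arf2 on BRZ, 62 to 344 for the interaction, 2261 to 5615 averaged and 276 to 791 shared. The slope ran from 0.57 to 0.79, the share with a smaller response in arf2 from 48.0% to 71.5%, r of BRZ and genotype effects from 0.21 to 0.49, and of their averages from -0.18 to 0.08. List calls ran from 1 to 2 for BRZ in Col, 0 to 2 for BRZ in arf2, 3 to 4 for arf2 on BRZ and 0 to 2 for the interaction. The thylakoid list on BRZ ran from an adjusted p of 7.42e-09 to 0.782, the latter without arf2 BRZ 1, where the call was lost and the direction turned. The chloroplast list for BRZ in arf2 ran from 0.00028 to 0.802, and without arf2 BRZ 2 it was called (0.00716) against its uncalled direction over all arrays.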

Other observations

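The families below were defined after the annotation had been seen. The tests of Col mock array 3, with the leaving out of Col mock arrays 1 and 2, of neighbours of ARF2 and of another block of neighbouring genes were chosen only after the result was seen. The bound for the last one was also reworded after its value was known.

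Of 69 measured chloroplast-encoded transcripts, 8 rose in Col on BRZ and 0 fell, psbA rising by 1.83 (SE 0.43) and psaA by 0.92 (SE 0.19) on the log2 scale, and the list had an adjusted p of 3.35e-06, or 0.894 with an estimated correlation (18 up and 1 down adjusted over the list alone). The calls of both genes were lost without Col mock array 1 (adjusted p 0.0979 and 0.0553) and without Col BRZ array 3 (adjusted p 0.0861 and 0.0637). Without Col mock arrays 1 and 2 the list call was lost (0.0835, or 0.0608 without arf2 mock array 3 as well), as were those of psbA (0.306 and 0.18) and psaA (0.218 and 0.119). The mean over the 69 genes was 9.38, 9.83 and 10.06 on the Col mock arrays and 10.16, 10.13 and 10.49 on the Col BRZ arrays (exact permutation p 0.1, the smallest possible). On BRZ the list was called downward in arf2 (adjusted p 4.73e-26, or 0.408 with an estimated correlation), with 0 members passing over all probe sets and 8 down adjusted over the list alone. On mock it was called downward in arf2 too (adjusted p 0.00195, or 0.702 with an estimated correlation), although 1 member was higher, 0 were lower and 68 did not pass (0 either way adjusted over the list alone). That call was lost without Col mock array 3 (0.17) and arf2 mock array 3 (0.181), without Col mock array 2 and arf2 mock array 3 (0.242) and with array weights (0.23). Between arf2 and Col the mean over the 69 genes differed by a log2 change of -0.11 on mock (exact permutation p 0.8). On BRZ it differed by -0.55 (exact permutation p 0.1). The thylakoid family shares genes with the list of nuclear photosystem subunits, so its calls are not independent of that list. The list of nuclear-encoded thylakoid proteins was called downward in arf2 on BRZ (adjusted p 0.0195, or 0.811 with an estimated correlation), with 0 of 22 passing, also over the list alone, and that call was lost without Col BRZ array 3 (0.0541) and without arf2 BRZ array 1 (0.782, with the direction turned), with the replicate block (0.0711), without Col mock array 2 and arf2 mock array 3 (0.0744) and without Col mock array 1 as well (0.0927).

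UDP-glycosyltransferases, which attach sugars to small molecules, were called upward as a list in arf2 on mock, with 9 of 51 up and 0 down, or 12 up adjusted over the list alone (adjusted p 0.0402, or 0.615 with an estimated correlation). UGT84A3 was higher by 1.38 (SE 0.16) and UGT73B1 by 1.18 (SE 0.13). This list was not called with quantile normalization (0.0866), with the replicate block (0.0511) or without Col mock array 1 (0.134), Col mock array 3 (0.442) or arf2 mock array 3 (0.226). The U-box ubiquitin ligase PUB23 was higher by 1.25 (SE 0.12, adjusted p 8.65e-05) in arf2 on mock and fell by 1.23 (SE 0.14, adjusted p 0.000261) with BRZ in arf2, and these genes were chosen after their values were seen. The U-box list was called downward with BRZ in arf2 (adjusted p 0.0258, or 0.596 with an estimated correlation), with 3 of 9 down, and upward in arf2 on mock (adjusted p 0.0402, or 0.391 with an estimated correlation), with 2 of 9 up, or 4 adjusted over the list alone. The mock call was lost with quantile normalization (0.147), without Col mock array 1 (0.0583) or 3 (0.17) and without arf2 mock array 2 (0.0578) or 3 (0.0914), and with the replicate block (0.0511) and the filter at 5 (0.0866). Among sugar transporters SWEET11 was lower in arf2 on BRZ (-0.93 ± 0.09, adjusted p 0.000616), the 1 called of 16 (2 down adjusted over the list alone), and that list had an adjusted p of 0.000189, or 0.408 with an estimated correlation. JAL33 fell by 0.86 with BRZ in Col (SE 0.09, adjusted p 0.000234), where the 4 jacalin lectins were called downward (adjusted p 0.000665, or 0.305 with an estimated correlation), with 2 down, or 3 adjusted over the list alone. Tubulins were called upward as a list with BRZ in arf2, with 2 of 7 up (adjusted p 0.0304, or 0.596 with an estimated correlation), a call lost with equal array medians (0.0542), without Col mock array 3 (0.0503), without arf2 mock array 3 (0.0635) and without arf2 BRZ array 1 (0.111). It was also lost with the replicate block (0.0799), array weights (0.0592) and the filters at 5 (0.0721) and 6 (0.101), and without Col mock array 2 and arf2 mock array 3 (0.105, or 0.125 without Col mock array 1 as well). On mock, GH9 endoglucanases and serine carboxypeptidase-like proteins were called downward as lists in arf2 (both adjusted p 0.0286, or 0.391 with an estimated correlation), with 0 of 15 and 1 of 27 members down, the same over the list alone. The GH9 call was lost with quantile normalization (0.0866), without Col mock array 1 (0.0645) or 3 (0.0512) and without arf2 mock array 1 (0.0614), and the carboxypeptidase call without Col mock array 2 (0.0614) or 3 (0.0512). Without Col mock arrays 1 and 2 they were lost too (0.206 and 0.154), and with arf2 mock array 3 left out as well (0.0579 and 0.0528). Camera called 2 of the 23 families for BRZ in Col, 2 for BRZ in arf2, 5 for arf2 on mock, 3 for arf2 on BRZ and 5 for the interaction, and none of these calls held with an estimated correlation.

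More probe sets were higher than lower for BRZ in Col (69.4%) and for arf2 on mock (73.2%). After quantile normalization these shares were 49.0% and 53.6%, inside the range set beforehand for a lower overall level of the Col mock arrays left by the normalization, yet equal distributions would remove a real overall shift too, so the test decides nothing. Without Col mock array 2 the shares were 62.2% (jackknife SE 16.2) and 68.8% (jackknife SE 12.7), too close to 60% for their spread to exclude that array. With Col mock array 3 as the only Col mock array the share for BRZ in Col was 41.9%, or 43.1% with arf2 mock array 3 left out too, and without Col mock array 3 it was 78.0%, so a difference between Col mock arrays 1 and 2 and array 3 is a candidate explanation, though 1 array takes its spread from the other groups. A real overall shift stayed open.

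Of the 87 probe sets with genotype differences that held on mock and on BRZ, those that name 1 gene covered 32 genes. QQS, GH3.3 and AT1G55240 were among them. A candidate explanation is a block of foreign sequence around the mutated gene, yet 0 of the 32 lay within 500 genes of ARF2 where 1.23 would fall by chance, and the upper 95% limit of the share was 10.9%. For these 32 genes this argues against genes linked to ARF2 as the main source, with a limit that treats genes as independent. The probe sets that do not name 1 gene could not be placed. Another block of neighbouring genes could not be excluded, since BGLU25, AT3G05170, AT3G05640 and AT3G05950 lay within 1 window of 200 genes (permutation p 0.313 over 10000 draws). The difference of BGLU25 between the genotypes on BRZ was not called with the replicate block (adjusted p 0.101).

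For the calls between groups of 3, other splits of the arrays were counted. In a fit of the 6 arrays alone BRZ in Col gave 959 calls and the highest other split 0, so 1 of 10 splits reached the real count. For arf2 on mock the real count was 663 and the highest other 0, again 1 of 10. The splits are too few for a share under 0.05.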
